A study of Mus musculus with 6 samples.

How the data were processed

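Expression was measured in total brain RNA of 6 mice, 1 array each: 3 controls with 1 floxed Elavl1 allele and 3 neuron-specific knockouts with both alleles floxed. Per the labels' protocols, RNA was extracted with TRIzol, 150 ng was labelled with the Affymetrix WT Plus kit, and the array was the Mouse Gene 2.0 ST type; the series' design text reports strong Cre reporter expression 21 days after the first tamoxifen dose. The deposited table holds intensity values on a linear scale for 41340 probesets. MAS5 is named in the submitters' processing notes, with no version; the background correction, the scaling target and any filter are not given in the sources used here. The labels describe separate samples without naming animals one by one, so p values measure the spread between these samples. Scan dates and batches are not given in the sources used here.

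Values were transformed as log2(intensity + 1). The rule fixed beforehand called for quantile normalization where array medians differed by more than 0.1 on the log2 scale, and they differed by 0.12. The probe annotation table listed 25335 of the probesets, 23521 with 1 gene symbol and 1814 with several, and the other 16005 are unnamed here. Probesets with 1 symbol gave 22180 genes, each represented by its probeset with the highest mean, and genes under the 25th percentile of mean level (5545) were left out, leaving 16635. Of these, 16523 were matched by gene identifier to the mouse RefSeq table of assembly GRCm38.p6, used for chromosome and neighbour only, and 0 symbols differed. Probesets without exactly 1 symbol were tested separately: of 8815 above the same brightness limit, 0 passed the adjusted threshold and 284 had an unadjusted p under 0.05. The table has 0 columns of per-sample values that were not used.

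Knockout and control were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Elavl1 also had a two-sided exact permutation test over 20 assignments. Gene lists, 46 in number and all with at least 4 tested members, were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the lists; camera with an estimated correlation and fry were alternatives. A fold is on the log2(intensity + 1) scale and understates changes of dim genes. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Apart from choices named below as made after the data had been seen, the groups, tests, lists, alternatives and naming rule were set before the data were examined.

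The rule named the ELAV family, then per direction up to 10 genes past the adjusted threshold, filled with the smallest unadjusted p among genes whose groups did not overlap, and then, for each list described, the 2 to 4 members with the smallest p and the leading marker of a cell type. The leading marker was taken as the first gene of a cell type list, a reading settled after the data had been seen. Tardbp, Prph and C4b fall under the list part of the rule. Predicted loci, small RNA genes, receptor families and sex-linked genes were passed over, 1 in the higher and 7 in the lower direction.

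Replicate numbers in the labels were checked for pairing. Deviations from the group means correlated at 0.31, 0.37 and 0.75 for the numbers 1, 2 and 3, all above the limit of 0.1 set for pairing, so the numbers were taken to pair the arrays. The pairing comes from this check and not from a label. It is specific for number 3 alone, since control 1 correlated with knockout 2 at 0.40 and control 2 with knockout 1 at 0.37. With both arrays numbered 3 apart from the rest, the others deviate in a shared direction, so the limit of 0.1 told little about numbers 1 and 2. The comparison without pairs remained the reported one, and the value with the replicate number as a block is given where it changes a call or a count by more than 1.5 times.

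The procedure was tested on simulated data in 10 runs over 16635 genes with 200 genes changed. Without the block, 1.4%, 16.4%, 85% and 99.2% of genes changed 1.3-, 1.5-, 2- and 3-fold were recovered, with 7.8 false calls per run; with the block the shares were 19.6%, 83%, 99.6% and 100%, with 11.8 false calls. A list shifted by 0.2 on the log2 scale was called in 90% of runs without and 100% with the block, and 0.2 lists that had not been shifted were called per run. The simulated noise was independent between genes, so these list rates do not hold where members vary together. It was also independent between arrays, so without the block the separation of arrays numbered 3 became random spread. The gene rates hold for 200 genes changed at once and not for a lone gene. In the real arrays the estimated correlation was 0.32 for oligodendrocyte markers and 0.53 for the glucocorticoid response. It was 0.34 for monoaminergic neuron markers and 0 for the interferon response. Alternatives covered the normalization, the brightness filter, the probeset rule, the variance model, array weights, the replicate block, Xist as a covariate, a pseudocount of 16, the set tests, the threshold and leaving out each array.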

Results

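Whole-brain RNA was profiled on Affymetrix Mouse Gene 2.0 ST arrays from 3 control mice and 3 mice in which HuR, the RNA-binding protein encoded by Elavl1, could be deleted in neurons. Both groups carried a tamoxifen-inducible Cre recombinase with a yellow fluorescent reporter under the neuronal Thy1 promoter. Controls had 1 floxed Elavl1 allele and are called control here, and mice with both alleles floxed are called knockout. Tamoxifen was given to both groups at 10 and 11 weeks of age, and brains were taken at 91 days. The table held intensities of 41340 probesets on each of the 6 arrays, with array medians from 13.4 to 14.6, and 16635 genes were tested. The 95% confidence interval of a log2 fold change had a median half-width of 0.33, or 0.24 when arrays with the same replicate number were treated as pairs. The arrays bear out this pairing for number 3 alone, so all results with pairs rest on an arbitrary matching of the other numbers. The arrays numbered 3 in both groups stood apart from the other 4: their log2 level of Xist, the RNA that silences an X chromosome, was 7.69 in the control and 7.68 in the knockout, against 2.52 to 2.79 elsewhere. The labels give mice of either sex and no sex per sample. With low Y-linked transcripts as well, the arrays numbered 3 read as female and the other 4 as male, with 1 female array in each group. Leaving out control 3 or knockout 3 therefore leaves an array numbered 3 in 1 group only, and calls made that way also carry this separation.

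The targeted gene was examined first. Elavl1 had an intensity of 309 ± 66.7 in control brain and 300 ± 13.8 in knockout brain (SD, n = 3 each). The log2 fold change of knockout over control was -0.05 with a standard error of 0.15, and its sign turned to 0.014 when arrays were centred on their median. The 95% confidence interval ran from -0.39 to 0.29, which is 0.763-fold to 1.22-fold, and the two-sided exact permutation p was 0.7, where 3 against 3 arrays allow no p below 0.1. On the log2 scale the difference was smaller than the SD of the control arrays (0.261) and about as large as that of the knockout arrays (0.046). Elavl1 is read by 1 probeset, whose position relative to the deleted exons is not given in the sources used here, cells other than neurons keep the gene, and the controls lack no more than 1 allele, so the measurement does not check the labels. The neuronal relatives Elavl2, Elavl3 and Elavl4 had log2 fold changes of -0.01, 0.04 and -0.04, each within a standard error of 0.16 to 0.21; with arrays centred on their median the values of Elavl2 and Elavl4 turned positive, and that of Elavl2 also did so with values as deposited. Leaving out control 3 gave an Elavl1 value of 0.08, leaving out control 2 one of -0.18, and leaving out knockout 2 one of -0.027.

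**Figure D1:**
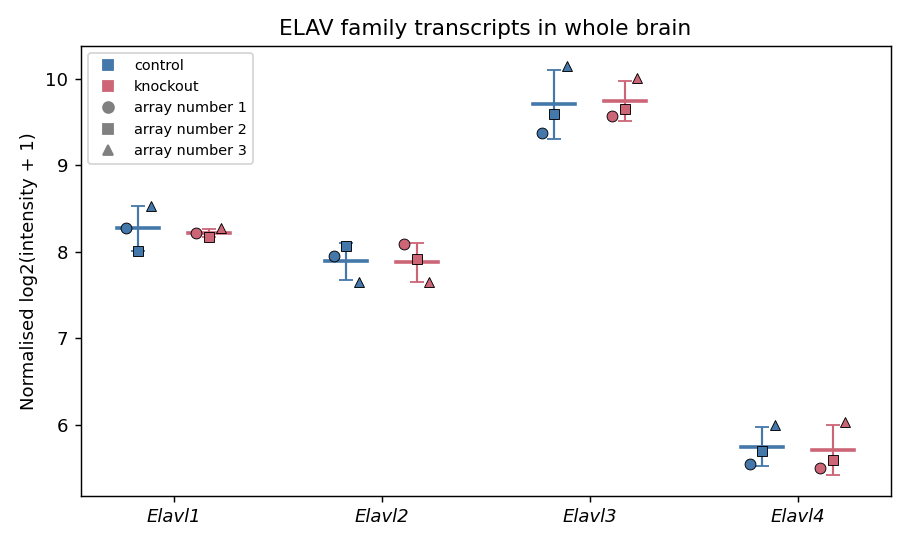
Normalised log2(intensity + 1) of the 4 ELAV family genes on each array; colours mark the groups, symbols the replicate numbers, and horizontal and vertical bars the mean and SD of 3 arrays. Control and knockout values overlap for each gene, with differences of the means of -0.05 for Elavl1, -0.01 for Elavl2, 0.04 for Elavl3 and -0.04 for Elavl4; the signs for Elavl1, Elavl2 and Elavl4 turn when arrays are centred on their median, and that for Elavl2 also with values as deposited.

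The interferon response list was called upward in knockout brain, with the preset correlation only. Of its 14 tested members, 10 had values above 0, with a median log2 fold change of 0.16 (camera with a preset correlation, adjusted p = 0.00634; p = 0.0199 and adjusted p = 0.914 with an estimated correlation). Bst2, which tethers budding virions to the cell surface, was 1.52-fold higher, with a log2 level of 4.58 ± 0.262 in control and 5.19 ± 0.1 in knockout brain (SD, n = 3 each), and all 3 knockout arrays lay above all 3 control arrays. Ifit1, an interferon-induced protein that binds viral RNA, had a fold of 1.52, and Oasl2, of the oligoadenylate synthetase family, 1.28. None of the members passed when adjusted over the list alone or over all genes. With same-numbered arrays as pairs, 3 members passed adjusted over the list alone, with limma adjusted p values of 0.00612 for Ifit1, 0.0214 for Bst2 and 0.0251 for Oasl2, and 0 passed over all genes. The matching of numbers 1 and 2 in these pairs is arbitrary. The list median was 0.13, 0.21 and 0.23 in the pairs numbered 1, 2 and 3. The list was no longer called without control 3 (adjusted p = 0.11), without knockout 1 (0.0627) or without knockout 2 (0.081).

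Among the 17 tested cytokines and chemokines, 14 had values above 0, and the list did not pass (camera adjusted p = 0.132), though it was called without the brightness filter (0.04), without control 2 (0.0454) and without knockout 3 (0.0127). Ccl3, a chemokine made by microglia and macrophages, had a log2 fold change of 0.51 with a standard error of 0.15, with no overlap between the groups, and tumour necrosis factor, Tnf, one of 0.22. With pairs, Ccl3 was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.0244; 0.165 without pairs). Of 14 antigen presentation and complement genes, 9 had values above 0 (median 0.057, camera adjusted p = 0.941; 0.0318 without knockout 3). The smallest p values there belonged to the peptide transporter Tap1, at -0.20, and to complement C4b, at 0.52 with a standard error of 0.33. The C4b value was 0.236 without control 3, 0.313 without knockout 2, 0.801 without control 2 and 0.795 without knockout 3. C4b passed adjusted over the list alone with pairs (limma adjusted p = 0.0168) and not without them (0.937).

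Monoaminergic neuron markers were called upward in knockout brain, with the preset correlation only. Of 11 tested members 10 lay above 0, with a median log2 fold change of 0.087 (camera with a preset correlation, adjusted p = 0.0187; p = 0.191 and adjusted p = 0.979 with an estimated correlation). The largest values belonged to serotonergic genes. Tph2, the rate-limiting enzyme of serotonin synthesis in the brain, had a log2 level of 4.94 ± 0.311 in control and 5.74 ± 0.535 in knockout brain (SD, n = 3 each), a 1.74-fold difference. Slc6a4, the serotonin transporter, had a log2 fold change of 0.64 ± 0.29 (SE), and Dbh, which converts dopamine to noradrenaline, one of 0.38 ± 0.15. Th, the rate-limiting enzyme of catecholamine synthesis, was at a log2 fold change of 0.05 with a standard error of 0.20. No member passed adjusted over the list alone, and with pairs Tph2, Dbh and Slc6a4 did, each at a limma adjusted p of 0.019. The median over the list was 0.26 and 0.42 in the pairs numbered 1 and 2 and 0.013 in the pair numbered 3. The list call was lost with arrays centred on their median (adjusted p = 0.0507) and without control 1 (0.185), control 2 (0.415), knockout 2 (0.22) or knockout 3 (0.217). The list median was 0.169 without control 3, 0.208 without knockout 1 and 0.147 without knockout 3, and Slc6a4 was at 0.964 without control 3.

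**Figure D2:**
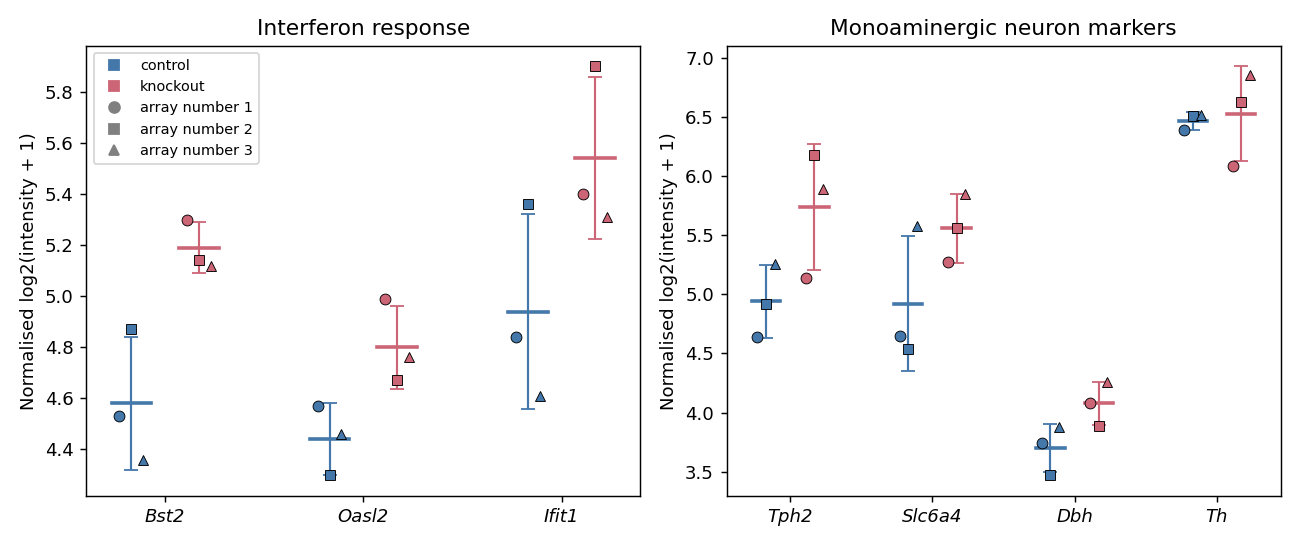
Normalised log2(intensity + 1) of 3 interferon response genes (left) and 4 monoaminergic neuron markers (right) on each array; colours mark the groups, symbols the replicate numbers, and bars the mean and SD of 3 arrays. For Bst2, Oasl2 and Dbh the 3 knockout arrays lie above the 3 control arrays, whereas Ifit1, Tph2 and Slc6a4 overlap between the groups and are higher in knockout within each same-numbered pair; Th has a mean difference of 0.05.

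Oligodendrocyte markers were called downward in knockout brain, with the preset correlation only. Of 13 tested members 11 lay below 0, with a median log2 fold change of -0.19 (camera with a preset correlation, adjusted p = 0.000728; p = 0.107 and adjusted p = 0.979 with an estimated correlation). Opalin, a membrane protein of myelinating oligodendrocytes, had a log2 level of 7.52 ± 0.343 in control and 6.93 ± 0.124 in knockout brain (SD, n = 3 each), a fold of 0.668. The tight junction protein Cldn11 had a log2 fold change of -0.25 and the myelin proteolipid Mal one of -0.20, both without overlap between the groups. Mbp, the major myelin basic protein gene, was at 0.012 with a standard error of 0.11. The median was -0.32 in the pair numbered 1, -0.004 in the pair numbered 2 and -0.12 in the pair numbered 3, and without control 1 the list was not called (median -0.089, adjusted p = 0.117) and Opalin was at -0.383. No member passed adjusted over the list alone, with or without pairs.

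The glucocorticoid response list was called upward in knockout brain, with the preset correlation only. Of 14 tested members 13 lay above 0, with a median log2 fold change of 0.16 (camera with a preset correlation, adjusted p = 0.00185; p = 0.21 and adjusted p = 0.979 with an estimated correlation). Its members with the smallest p values were the transcription factor Zbtb16, with a log2 fold change of 0.56 ± 0.23 (SE), the mTOR inhibitor Ddit4 (0.39 ± 0.22), the lipid droplet protein Plin4 (0.23 ± 0.15) and the kinase Sgk1 (0.56 ± 0.37). The pairs numbered 1 and 2 had list medians of 0.22 and 0.39, and the pair numbered 3 had -0.13. The call was lost without control 1 (adjusted p = 0.0983) and without knockout 2 (0.534). The list median was 0.088 without knockout 2 and 0.302 without knockout 3. Without knockout 2 Ddit4 was at 0.219, Plin4 at 0.09 and Sgk1 at 0.346, without knockout 3 Ddit4 was at 0.613 and Sgk1 at 0.996, and without knockout 1 Sgk1 was at 0.343. No member passed adjusted over the list alone with or without pairs.

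Stress response lists did not pass. In the unfolded protein and integrated stress response, 13 of 17 members lay above 0 with a median of 0.07 (camera adjusted p = 0.0722), and the endoplasmic reticulum genes Sdf2l1, Herpud1 and Manf had log2 fold changes of 0.35, 0.33 and 0.22. Of 13 heat shock protein genes 11 lay above 0 (median 0.13, camera adjusted p = 0.132), among them the inducible chaperone Hspa1b at 0.55 ± 0.24 (SE) and its co-chaperone Bag3 at 0.16. Both lists were called with arrays centred on their median (camera adjusted p = 0.0194 for the unfolded protein and integrated stress response and 0.0478 for heat shock proteins), with values as deposited (0.029 and 0.0431) and without knockout 3 (0.00864 and 0.00165). The first was also called in the upper 50% of genes (0.0288) and with a pseudocount of 16 (0.026), and the heat shock proteins with array weights (0.016) and without both arrays numbered 3 (0.00625).

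The title of the series names motor neuron disease, and the lists closest to that question did not pass. Of 9 motor and cholinergic neuron markers, 8 lay above 0 with a median of 0.049 (camera adjusted p = 0.805). The intermediate filament Prph had a log2 fold change of 0.27 ± 0.18 (SE), the transcription factor Isl1 -0.15 ± 0.18 and Chat, which makes acetylcholine, 0.066 ± 0.23. Genes linked to amyotrophic lateral sclerosis (16 tested) had a median of 0.037 (camera adjusted p = 0.805), with Hnrnpa2b1 at 0.15, Pfn1 at 0.13 and Tardbp, which encodes TDP-43, at 0.068. Transcripts reported to bind HuR (28 tested) had a median of 0.043 (camera adjusted p = 0.748), with Tnf at 0.22, Ptgs2 at 0.28 and Nos2 at -0.26. Of 17 apoptosis genes 12 lay above 0 (median 0.018, camera adjusted p = 0.748), among them Bcl2l1 at 0.16 and Bbc3 at 0.13. All 14 pan-neuronal markers lay above 0, at a median of 0.047 (camera adjusted p = 0.748; 0.00871 without control 3, at a median of 0.2), with Nefm at 0.22 (0.003 without knockout 3, 0.511 without control 3), Uchl1 at 0.073 and Rbfox3 at 0.009. A median near 0 does not exclude changes in a small share of the cells of whole brain.

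Lists of microglia, astrocytes, meningeal fibroblasts and immediate early genes were likewise not called. Microglia and macrophage markers had a median of 0.015 (15 tested, camera adjusted p = 0.964, with the test pointing down), with the mannose receptor Mrc1 at 0.40 ± 0.27 (SE), P2ry12 at -0.21 ± 0.28 and Aif1 at 0.042. That list of microglia and macrophage markers was called downward without control 3 (median -0.139, adjusted p = 0.0347) and upward without knockout 3 (0.153, adjusted p = 0.00685). Astrocyte markers had a median of 0.035 (13 tested, camera adjusted p = 0.845; 0.0453 without knockout 3), with Gfap at 0.15 and the water channel Aqp4 at 0.10, and reactive astrocyte genes one of 0.011 (13 tested, camera adjusted p = 0.905). Meningeal fibroblast markers had the highest median, 0.20 (13 tested, camera adjusted p = 0.376), with collagens Col3a1 at 0.25 and Col1a1 at 0.36, the latter at 0.009 without knockout 1, 0.183 without control 3 and 0.669 without knockout 3. The list medians of meningeal fibroblast markers were -0.259, 0.281 and 0.277 in the pairs numbered 1, 2 and 3, and the sign turned without control 3 (-0.168) or knockout 2 (-0.092). The meningeal fibroblast markers were called without control 1 (adjusted p = 0.00432), without knockout 3 (0.000255) and with Xist as a covariate (0.0408). Immediate early genes had a median of -0.052 (20 tested, camera adjusted p = 0.748; 0.00272 without control 2), with Junb at -0.30 and Egr3 at 0.25. In all, 4 of 46 lists were called with the preset correlation, and 0 with an estimated correlation, with fry one way (smallest adjusted p = 0.556) or with fry in either direction (0.902). The estimated correlation called no list even where arrays numbered 3 were compared with the others, so its lack of calls decides little. Of the 10 splits of the 6 arrays into 3 and 3, the real one included, 6 gave as many called lists with the preset correlation. Medians of the 42 lists that were not called ran from -0.072 to 0.20, and in 10 of them the median, the mean and the test did not share a sign.

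**Figure D3:**
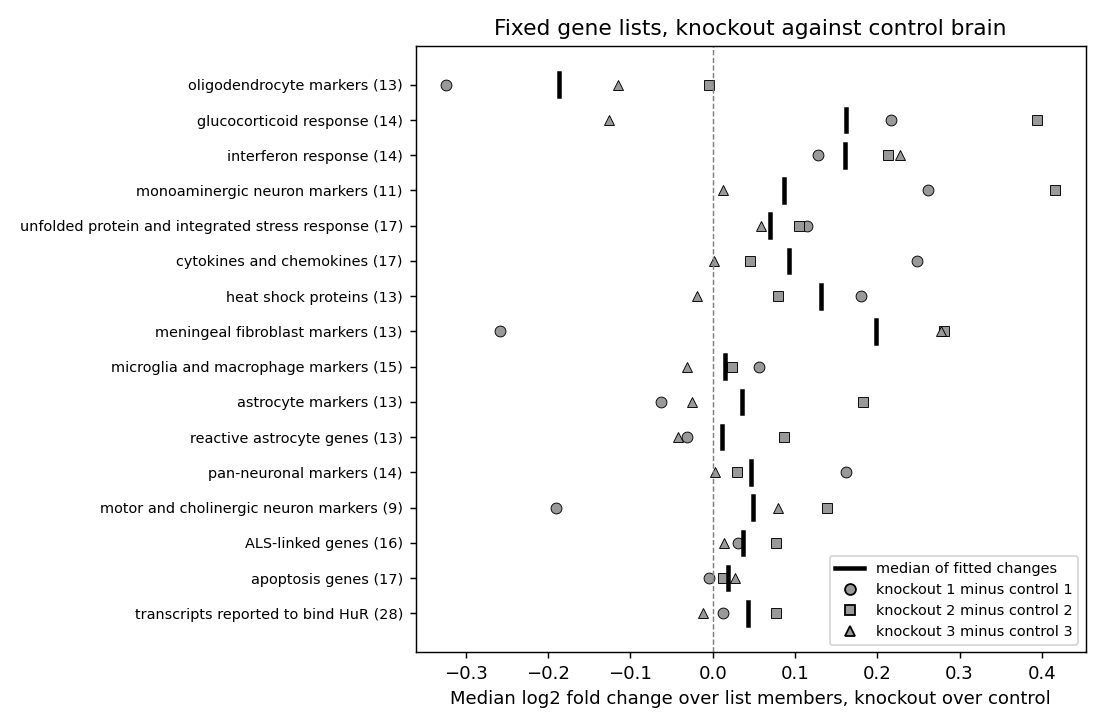
Median log2 fold change of knockout over control for 16 fixed gene lists, with the number of tested members in parentheses; black bars give the median of the fitted changes and grey symbols the median within each same-numbered pair. The interferon list has medians of 0.13, 0.21 and 0.23 in the 3 pairs, the oligodendrocyte list lies at -0.19, and the glucocorticoid list has a median of -0.13 in the pair numbered 3.

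Gene by gene, 0 of 16635 genes passed a Benjamini-Hochberg adjusted p of 0.05 in limma, with or without pairs. At an unadjusted p under 0.05 there were 282 genes (155 higher and 127 lower in knockout), or 1.7% of those tested, where 832 would be expected by chance. Each group holds 1 array numbered 3, and without pairs the separation of those arrays counts as spread within groups. The count under the expected one is therefore no finding about genotype. With pairs there were 806 (468 higher and 338 lower), or 4.85%, and with Xist as a covariate 766, or 4.6%. The higher share of the 282 was 55%, against 42.1% with values as deposited and 68.6% with arrays centred on their median. Among genes whose groups did not overlap, those with the smallest unadjusted p were, higher in knockout, Flywch2 (fold 1.43), the collagen-modifying Crtap (1.48), Glt8d2 (1.34), phospholipase D Pld1 (1.43), Pmf1 (1.35), Bst2 (1.52), the ADP-ribosyltransferase Parp3 (1.34), Egfl6 (1.42), Nyap1 (1.36) and Sbspon (1.45). Lower in knockout were the zinc finger gene Zfp939 (0.645), Scgb1b3 (0.715), the lens filament gene Bfsp1 (0.758), Rskr (0.751), the lectin receptor Clec4a3 (0.681), Trim54 (0.786), Opalin (0.668), Galnt4 (0.759), Chst5 (0.785) and Trim43c (0.739). These are values and not calls, since each had an adjusted p of 1. Several are also dim, near the array medians of 3.85 to 3.97 on the log2 scale before normalization. Clec4a3 averaged 3.73 in control and 3.18 in knockout brain, Trim43c 3.95 and 3.51, Pmf1 3.69 and 4.12, and Sbspon 3.76 and 4.3. Groups did not overlap in 948 genes, or 5.7%, where chance gives 10% for arrays that are alike apart from genotype. With 1 array numbered 3 in each group this does not hold, so the 2 shares cannot be compared. In simulated data with 200 genes changed at once and noise independent between genes and arrays, 85% of genes changed 2-fold were recovered without pairs. Of those changed 1.5-fold, 16.4% were recovered. With pairs 99.6% and 83% were recovered. Without pairs the simulation turned the separation of arrays numbered 3 into random spread, unlike the real arrays. These shares are therefore not the chance of finding a lone changed gene in the real arrays. Leaving out control 3 (574 genes), knockout 1 (185), knockout 2 (163) or knockout 3 (463) moved the unadjusted count by more than 1.5 times, and leaving out both arrays numbered 3, an alternative chosen after the data had been seen, gave 854 with 0 past the adjusted threshold.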

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

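Leaving out both arrays numbered 3, and the set tests with an estimated correlation or fry combined with the replicate block, were chosen after the data had been seen. The number of genes past the adjusted threshold was 0 under each normalization, filter, probeset rule, variance model, weighting, covariate, pseudocount and left-out array; it becomes 282 at an unadjusted p under 0.05 and 10 with a change of at least 1.5-fold added, which follows from the looser threshold. The unadjusted count was 254 with values as deposited, 242 with arrays centred on their median, 465 without the filter (more genes tested), 88 in the upper 50% of genes (fewer tested), 755 with array weights, 766 with Xist as a covariate and 214 with a pseudocount of 16. With the replicate block 0 genes passed, 806 had an unadjusted p under 0.05, Elavl1 stayed at -0.05 and 4 lists were called, so the block changed no other call of a gene or list over all those tested. Elavl1 turned to 0.014 with arrays centred on their median, 0.025 with array weights and 0.058 without both arrays numbered 3, and ran from -0.18 to 0.08 when single arrays were left out; the cause was not tested.

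The 4 called lists became 0 with camera and an estimated correlation, 0 with fry in 1 direction and 0 with fry in either direction. They also became 0 with an estimated correlation or fry together with the replicate block. The estimated correlation allows list members to vary together. For the interferon response it was 0, yet the camera p still moved from 0.000414 to 0.0199. Members that vary together therefore do not explain the loss of that list. With 6 arrays the estimated correlation called no list even for arrays numbered 3, so its lack of calls decides little. Leaving out single arrays gave 1 to 16 lists: 2 without control 1, 7 without control 3, 1 without knockout 2 and 16 without knockout 3. Without control 3 or knockout 3, an array numbered 3 remained in 1 group only, so genotype was mixed with what sets those arrays apart. Microglia and macrophage markers, at -0.49 in arrays numbered 3, were called downward without control 3 and upward without knockout 3. Pan-neuronal markers, at 0.44 there, were called upward without control 3. For the other arrays the cause was not tested. Elavl2 turned to 0.023 with values as deposited, 0.058 with median centring and 0.013 with array weights, and Elavl4 to 0.012 with median centring. Th turned to -0.094 with array weights and -0.092 without both arrays numbered 3. The median of reactive astrocyte genes turned to -0.019 with values as deposited, that of motor and cholinergic markers to -0.036 without both arrays numbered 3, and that of immediate early genes to 0.079 with array weights and 0.159 without both arrays numbered 3. The cause was not tested for any of these.

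Other values changed sign when 1 array was left out. Genes ran from -0.126 to 0.113 for Elavl2, -0.125 to 0.257 for Elavl3, -0.205 to 0.084 for Elavl4, -0.001 to 0.12 for Uchl1, -0.129 to 0.187 for Rbfox3, -0.057 to 0.056 for Mbp, -0.129 to 0.256 for Chat, -0.06 to 0.14 for Aif1, -0.117 to 0.272 for Th and -0.506 to 0.002 for P2ry12. List medians ran from -0.055 to 0.2 for pan-neuronal, -0.087 to 0.192 for motor and cholinergic, -0.139 to 0.153 for microglia and macrophage markers, -0.168 to 0.376 for meningeal fibroblast markers, -0.104 to 0.202 for antigen presentation, -0.177 to 0.157 for immediate early, -0.006 to 0.12 for astrocyte, -0.023 to 0.104 for reactive astrocyte and -0.002 to 0.102 for HuR-bound transcripts. Other values that kept their sign and moved by over 1.5 times ran from 0.003 to 0.511 for Nefm, 0.009 to 0.669 for Col1a1, -0.281 to -0.001 for Isl1, 0.081 to 0.426 for Prph, 0.153 to 0.602 for Mrc1, 0.029 to 0.237 for Gfap, 0.031 to 0.177 for Aqp4, 0.056 to 0.241 for Pfn1, 0.016 to 0.126 for Tardbp, 0.109 to 0.234 for Hnrnpa2b1, 0.142 to 0.378 for Ptgs2, -0.378 to -0.106 for Nos2, 0.068 to 0.228 for Bcl2l1, 0.076 to 0.165 for Bbc3, 0.402 to 0.843 for Hspa1b, -0.273 to -0.12 for Tap1 and 0.161 to 0.397 for Egr3. Medians of lists that were not called, also with the sign kept, ran from 0.012 to 0.056 for ALS-linked genes, 0.024 to 0.068 for apoptosis genes, 0.056 to 0.155 for heat shock proteins, 0.067 to 0.121 for the unfolded protein and integrated stress response and 0.04 to 0.147 for cytokines and chemokines. Signal over background was not given per probeset, and dim genes such as Dbh and Ccl3 lie near the low end of the scale.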

Other observations

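The comparison of arrays numbered 3 with the others, the snoRNA set, and the tests on sex-linked genes, on batch, on single arrays behind the serotonergic difference and on splits for the adjusted gene count were chosen after those results had been seen. The arrays numbered 3, 1 control and 1 knockout, differed from the other 4 in far more genes than the genotypes did. With genotype in the limma fit, 3055 genes passed an adjusted p of 0.05, 1742 higher and 1313 lower; since the arrays were singled out because they differ, this describes the 6 arrays and is no test of a condition. Of 17 sodium, potassium and calcium channel genes 15 were higher past the threshold, with a median log2 difference of 0.83 (Kcna2 1.57, Scn1a 0.90). Synaptic vesicle genes had a median of 0.66, cerebellar markers 0.85 (Cbln1 1.45) and endothelial and mural cell markers 0.86 (Flt1 1.95). Meningeal fibroblast markers were lower, with a median of -0.73 (Dcn -1.03), as were microglia markers, at -0.49 (C1qa -0.74), ribosomal proteins, at -0.28 with 9 lower past the threshold and 0 higher, and oxidative phosphorylation subunits, at -0.2 with 8 lower and 0 higher. A pair of the lists called between the genotypes also differed here with the preset correlation, the glucocorticoid response at -0.23 (camera adjusted p = 0.0285) and monoaminergic neuron markers at 0.29 (0.0412). With camera and an estimated correlation none of the 46 lists passed (smallest adjusted p = 0.186). That includes the channel genes, with 15 of 17 past the threshold gene by gene. With 6 arrays this test could hardly call a list, so its lack of calls does not show that the lists were alike. The glycinergic hindbrain genes Glra1 and Slc6a5 were also higher in arrays numbered 3, by 2.47 and 2.48.

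Small nucleolar RNA genes, which guide the chemical modification of ribosomal RNA, were lower in arrays numbered 3: 64 of 73 passed the adjusted threshold downward and 0 upward, with a median log2 difference of -1.02 (Snora73b -2.26). They were also lower in knockout than in control brain within each pair, with medians of -0.25, -0.19 and -0.16 in the pairs numbered 1, 2 and 3, and a median of -0.17 with 61 of 73 genes below 0. Camera gave p = 1.65e-06 with the preset correlation and p = 0.469 with an estimated one, and with the replicate block 9.76e-20 and 0.0228. The set was chosen after its low level had been seen, so these p values describe it and test nothing. Its genes varied together, with an estimated correlation of 0.85 without the block. The values with the block also rest on the arbitrary matching of numbers 1 and 2.

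The separation of arrays numbered 3 could come from the animals' sex, from preparation or from what was dissected. Xist was high in exactly these arrays, and the Y-linked Uty was at 2.95 and 3.16 there against 7.22 to 7.53 in the others. By these transcripts the arrays numbered 3 come from females and the others from males. Genes on the X and Y chromosomes alone are argued against, since 96.3% of the genes past the threshold with a known chromosome lie on autosomes. For the snoRNA shift alone, a lower share of meninges as a cause stays open: with the meningeal marker mean as a covariate the snoRNA median moved from -1.02 to -0.85, and the bound set in advance, 1 SD over snoRNA genes (1.03), was met yet as wide as the shift itself, so it was judged afterwards to decide nothing. Since 0 of the other arrays reached the Xist level of arrays numbered 3, an effect of sex cannot be told apart from a batch of preparation, labelling or hybridisation. Sex as the source of the separation stays untested, and so does a difference in what was dissected. The hindbrain gene Slc6a5 was at 7.91 and 8.14 in arrays numbered 3, against 4.85 to 6.19 in the others. Glra1 was at 8.18 and 8.44 against 5.31 to 6.38. The brainstem and spinal cord marker Hoxa4 was not higher there, at 5.34 and 5.15 against 5.25 to 5.77, so these genes bear on dissection without deciding it.

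The lower snoRNA level in knockout brain may follow small RNA recovery or genotype. If it lay along the axis that sets arrays numbered 3 apart, the 200 other genes with the largest falls in those arrays would be expected at a median of -0.148 in knockout over control. They were at -0.002, with a standard error over genes of 0.02, on the side of the bounds set in advance that speaks against that axis. That error counts the genes as independent, and genes picked for falling together on the same 6 arrays are not. It is therefore too small, and the axis is not excluded as the cause. A preparation difference confined to small RNA and an effect of the HuR deletion both stay open, as neither was tested.

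The higher values of Tph2, Slc6a4 and Dbh in knockout brain did not pass an adjusted threshold without pairs. If real, they could reflect neurons of the raphe and locus coeruleus or how much brainstem was taken. The mean log2 fold change of Tph2, Slc6a4 and Dbh lay between 0.5 and 0.8 with any 1 of the 6 arrays left out, but these genes were picked because they were high and the call of the whole list was lost without each of 4 arrays in turn, so dependence on single arrays stays open. More brainstem in the knockout samples stays open: 14 tested brainstem and spinal cord markers, mostly Hox genes, had a median of 0.07 with a standard error of 0.051 and 9 above 0. Of these, 8 had a mean in control below the median of every array, too dim to follow the amount of tissue, so the bounds of 0.2 and 0.1 set in advance tested little, and the brighter Glra1 and Slc6a5 were at 0.35 ± 0.88 and 0.04 ± 0.91 (SE). A change in the neurons themselves was not tested.

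DNA carried along with the floxed allele was weighed as a source of differences near Elavl1. The 40 nearest tested genes had a median absolute moderated t of 0.67, at percentile 93.8 of 15704 windows of neighbouring genes, between the bounds of 90 and 95 set in advance, so the hypothesis stays undecided; 2 of them had an unadjusted p under 0.05.

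The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the adjusted threshold the real value was 0 and the highest other 0, so 10 of 10 splits gave as many. At an unadjusted p under 0.05 the real value was 282 and the highest other 2638, and 7 splits gave as many genes. For called lists the real value was 4 and the highest other 16, and 6 splits gave as many. The 4 splits with both arrays numbered 3 on one side gave 2049 to 2638 genes and 13 to 16 lists, which points to that structure of the samples. The other 3 splits that part all pairs gave 217 to 385 genes and 1 to 4 lists, and with the replicate block 660 to 1127 genes and 3 to 5 lists, against 806 and 4 for the real one.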
